A study of Mus musculus with 13 samples.

How the data were processed

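Plasma exosomal RNA of 13 mice (5 sham, 8 CLP, 24 hours post-surgery) was measured on a panel of 68 miRNA probes. Per the labels' protocols, exosomes were isolated by ultracentrifugation and RNA was extracted with a column kit. Per the same protocols, miRNAs were hybridized to FirePlex hydrogel particles, ligated to adapters, released and amplified by RT-PCR with a biotinylated primer. The deposited raw table holds fluorescence intensity on a linear scale, which the authors left unscaled between samples. The scanner, its software and any background subtraction are not given in the sources used here. Because the raw table holds exact zeros and no negative-control probe was found in it, it was treated as already background subtracted and 1 empty cell was left empty. The authors' second table, also of intensity, proved to be the raw values times 1 factor per sample (0.450 to 4.31). How that factor was chosen is not given in the sources used here. Its columns for CLP 6 and CLP 7 match the raw columns labelled CLP 7 and CLP 6, so which of these mice is which is unsettled. Both are CLP, so group means and group tests are not affected, and single-mouse values follow the labels of the raw table.

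The labels number the samples and the series design speaks of mice, so each sample was taken as 1 mouse. Beyond that, nothing states how mice were housed, bled or assayed, so p-values measure only the spread between these samples. The labels used here give no batch, plate, RNA input or plasma volume.

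Each sample was divided by the geometric mean of the 60 miRNAs above 0 in all samples and multiplied by the mean level. Values were then floored at the 5th percentile of positive scaled values (3.09 units), and log2 was taken. A fold change is therefore relative to the panel, and it understates the change of miRNAs near the floor. Scaling was preferred to quantile normalization because the panel is a small targeted set. The 65 miRNAs above the floor in at least 5 samples were tested, which left out miR-1246, miR-376b-3p and miR-523-5p. On the unscaled signal the floor was 2.10 units and 66 miRNAs were tested.

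Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, adjusted p under 0.05, no covariate). Every adjusted p of a single miRNA comes from limma unless the exact permutation test is named beside it. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. Per-mouse measures (raw signal, detected miRNAs, the ratio of miR-451a to miR-23a-3p, and spread) were compared by exact two-sided permutation over all 1287 splits.

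Of 23 lists of cell type markers and seed families, 21 had a tested member, and no member of the muscle and miR-103/107 lists was tested. The 12 lists with at least 3 tested members were tested by camera with a preset correlation of 0.01, with an estimated correlation and by fry. Named miRNAs were the 10 largest positive and 10 largest negative changes among those that passed, up to 2 members of each list with the smallest unadjusted p, and a fixed set of blood, liver, inflammation and hypoxia miRNAs, 38 in all. miR-20a-5p and miR-140-3p were named after their values were seen. The tests, lists, naming rule and most alternatives were fixed before the data were examined.

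The probes carry human miRNA names. A mouse gene of the same number and letter was found in the GRCm38.p6 gene table for 54 probes, of the same number only for 10, and for 4 none was found (miR-1246, miR-422a, miR-523-5p and miR-885-5p). Probe sequences were not used here, so cross-hybridization was not assessed.

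Alternatives changed 1 choice at a time: the scaling (quantile, none, median, 75th percentile, 3 most stable miRNAs, which were miR-20a-5p, miR-23a-3p and miR-93-5p, the authors' values), the floor, the filter, the test, a block for the replicate number and each mouse left out in turn. The 3 further ones were chosen after seeing the data: leaving out the 2 weakest sham samples, keeping the 43 miRNAs at 10 or more raw units in every sample, and a fit of the unscaled signal with the level of the sample as a covariate. Leaving each mouse out of the unscaled fit was also added then.

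The scaled fit was tested on simulated data of 65 miRNAs in 20 panels. Noise was drawn separately for each miRNA, and every miRNA followed the level of the sample with a slope of 1. The measured slopes differed between miRNAs (0.29 for miR-451a, 1.80 for miR-200a-3p), so the rates do not cover calls that arise from such differences. With no miRNA changed, 0% were called. With 15 changed, it called 20.4% of those changed by 0.5 log2 units, 77% at 1 and 99.0% at 2, and 0.631% of the unchanged ones. With 39 raised by 1 log2 unit, it called 20.1% of these (mean estimate 0.39) and 46.7% of the unchanged ones, whose mean estimate was -0.59: a broad rise makes unchanged miRNAs appear lower after scaling.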

Results

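MicroRNAs (miRNAs) carried by plasma exosomes, the small vesicles that cells release into the blood, were profiled in male wild-type C57BL/6J mice 24 hours after surgery. The surgery was either a sham operation (5 mice) or cecal ligation and puncture (CLP, 8 mice), in which the cecum is tied off and pierced so that gut bacteria seed a polymicrobial sepsis. Each mouse gave 1 sample, measured on a panel of 68 miRNA probes read as fluorescence. The summed raw signal of the panel ranged from 10598 to 45121 units in sham mice and from 33043 to 74685 units in CLP mice, and the number of mice limits the precision of every value.

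The first comparison asked whether the amount of miRNA signal recovered from plasma exosomes differed after CLP, before any scaling between mice. Nearly the whole panel was brighter in CLP mice. The geometric mean signal of a mouse was 3.83-fold higher in CLP, with a log2 mean of 8.47 ± 0.58 (SD, n = 8) against 6.53 ± 0.99 (SD, n = 5) in sham. All 66 miRNAs tested without scaling had a higher mean in CLP, and 60 of them rose in limma's moderated test with Benjamini-Hochberg adjustment, with a median change over all 66 of 1.87 log2 units. The largest unscaled rises were those of miR-10a-5p, encoded in a Hox gene cluster, at 15.1-fold (log2 3.92, SE 0.53) and of miR-200a-3p, an epithelial miRNA that represses the ZEB transcription factors, at 13.2-fold (log2 3.72, SE 0.64). Next came miR-146a-5p, a feedback inhibitor of Toll-like receptor signalling, at 7.02-fold, miR-126-3p, an endothelial miRNA, at 6.65-fold, miR-145-5p of smooth muscle at 6.58-fold and miR-122-5p, the main miRNA of hepatocytes, at 6.48-fold. The erythroid miR-451a (log2 0.44, SE 0.38, limma adjusted p = 0.272) and miR-16-5p (0.70, SE 0.38, limma adjusted p = 0.0844) were among the 6 miRNAs that did not pass, as were miR-205-5p (0.33) and miR-744-5p (0.69).

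An exact two-sided permutation test of the geometric mean signal over all 1287 splits of the mice gave p = 0.00155 (0.00622 after Benjamini-Hochberg adjustment over the 4 per-mouse measures), and the smallest p this design can give is 0.000777. The geometric mean lay above that of every sham mouse in 7 of 8 CLP mice. The exception was CLP mouse 8, and sham mouse 5 was the only sham mouse above it. Without the 2 weakest sham mice (sham 1 and sham 4), a comparison chosen after the data were seen, 37 of 66 miRNAs rose.

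**Figure D1:**
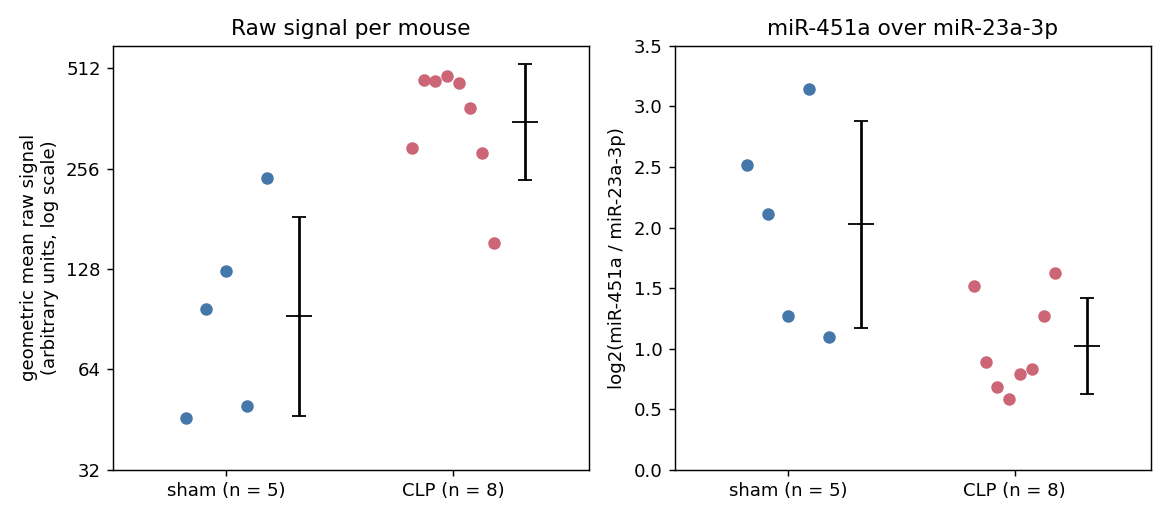
Left, geometric mean raw signal of each mouse (arbitrary units, log scale); right, log2 ratio of miR-451a to miR-23a-3p in each mouse; points are mice (sham n = 5, CLP n = 8), horizontal marks are group means and bars are SD. The raw signal was 3.83-fold higher in CLP and the ratio was 2.01-fold lower, with overlap between the groups in both panels.

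The second comparison asked which miRNAs differed relative to the rest of the panel, after each mouse was scaled to its geometric mean. Of 65 miRNAs tested, 7 rose and 13 fell. The largest relative rises were those of miR-200a-3p (4.47-fold, log2 2.16, SE 0.53, limma adjusted p = 0.00936) and miR-10a-5p (3.95-fold, log2 1.98, SE 0.22, limma adjusted p = 1.26e-05), each above the sham mean in 8 of 8 CLP mice. The raw signal of miR-200a-3p in sham mice ran from 0.19 to 36.2 units, and the lowest, in sham mouse 4, lay below the floor. Without that mouse miR-200a-3p was at 1.49, below miR-10a-5p at 1.87. miR-200a-3p and miR-10a-5p are the 2 miRNAs called higher under all 7 scalings compared, the unscaled signal and the authors' values included. The largest relative falls were those of miR-205-5p, a miRNA of stratified epithelium (3.05-fold lower, log2 -1.61, SE 0.46), miR-451a (2.84-fold lower, log2 -1.50, SE 0.32), miR-744-5p (2.38-fold lower, log2 -1.25, SE 0.22) and miR-16-5p (2.36-fold lower, log2 -1.24, SE 0.25). All 4 turn positive on the unscaled signal (0.33, 0.44, 0.69 and 0.70), and miR-16-5p also turns positive, at 0.14, under quantile normalization, where miR-451a did not pass (-0.22, limma adjusted p = 0.271; 0.000935 to 0.795 over all its alternatives).

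The other relative rises were smaller. miR-129-5p, a neuronal miRNA, rose by 1.01 (SE 0.33), from a raw mean of 1.496 units in sham to 12.9 units in CLP, near the low end of the panel. miR-146a-5p rose by 0.87 (1.83-fold, SE 0.25, limma adjusted p = 0.0192), and miR-126-3p by 0.80 (1.74-fold, SE 0.23, limma adjusted p = 0.0192). miR-125a-5p rose by 0.64 (SE 0.23) and miR-22-3p by 0.58 (SE 0.20).

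Among the other relative falls were 2 miRNAs with abundant expression in blood cells, miR-486-5p (log2 -0.76, SE 0.17, limma adjusted p = 0.0058; 1.17 on the unscaled signal) and miR-21-5p (-0.75, SE 0.22; 1.19 unscaled). miR-17-5p (-0.79) and miR-93-5p (-0.63), members of a family of shared seed sequence transcribed from polycistronic clusters, also fell after scaling and were positive, at 1.15 and 1.31, on the unscaled signal. The same held for miR-185-5p (-0.70; 1.24 unscaled), let-7g-5p (-0.64; 1.30), miR-23a-3p (-0.50; 1.44) and miR-24-3p (-0.48; 1.46). miR-20a-5p fell by 0.51, with 1.43 on the unscaled signal; it lies outside the naming rule and was named after its value was seen. Scaling to the 3 most stable miRNAs (miR-20a-5p, miR-23a-3p and miR-93-5p, which all fell with the geometric mean) sets the mean change of these 3 to 0, so their values near 0 there say nothing of their direction; miR-24-3p was at 0.067. Under all 7 scalings, the unscaled signal included, 12 of the 13 lay below the median miRNA. The exception was miR-16-5p, above it with quantile normalization (0.11). Every scaling other than quantile normalization applies 1 factor per sample or none, which shifts all miRNAs off the floor alike. Their agreement on the side of the median was thus largely fixed in advance, and only quantile normalization is a separate check. Unscaled values of miRNAs off the floor are the scaled ones plus the difference in level (1.94). A positive unscaled value is thus not evidence against a relative fall. Relative to the unscaled median, miR-451a lay at -1.44 and miR-10a-5p at 2.05.

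Several miRNAs with established links to sepsis or to blood cells did not pass after scaling. miR-122-5p was 0.98 higher (SE 0.44, limma adjusted p = 0.0996) with 4 sham values, since 1 cell of the table was empty. miR-145-5p was 0.78 higher (limma adjusted p = 0.0820), and miR-181a-5p 0.45 higher (0.0548 by the same test). miR-181a-5p and miR-150-5p were nevertheless called higher under 5 of the 7 scalings (with the authors' values, limma adjusted p = 0.0196 and 0.0261; over all alternatives 0.000153 to 0.432 and 0.000111 to 0.345), and miR-181a-5p also passed the exact permutation test (Benjamini-Hochberg adjusted p = 0.0267), in which miR-129-5p and miR-125a-5p did not (0.0652 and 0.0643). The 5 were quantile normalization, the 75th percentile, the authors' values, the 3 most stable miRNAs (28 miRNAs higher) and the unscaled signal (60 of 66 higher). The authors' values and the 75th percentile gave nearly the same change (0.665 and 0.671 for miR-181a-5p), so the 5 are not separate checks. In the scaled fit the values were 0.27 for miR-155-5p, which is induced in activated macrophages, 0.53 for the lymphocyte miR-150-5p and -0.63 for miR-192-5p of liver and gut epithelium, which was 1.30 without scaling. miR-223-3p of neutrophils was at -0.11 and the hypoxia-induced miR-210-3p at -0.12, but both were positive unscaled, with the 75th percentile, with the authors' values and with the 3 most stable miRNAs (0.44 and 0.43 in the last).

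The split of calls moved with the scaling. It was 7 higher and 13 lower with the geometric mean, 5 and 7 with quantile normalization, and 4 and 6 with median scaling. It was 13 and 6 with the authors' values, 13 and 6 with the 75th percentile, 28 and 3 with the 3 most stable miRNAs, and 60 and 0 unscaled. The calls of miR-205-5p, miR-21-5p, miR-185-5p and let-7g-5p as lower ended with the authors' values, the 75th percentile and the 3 most stable miRNAs (miR-205-5p at limma adjusted p = 0.0550, 0.0573 and 0.0990; 0.0125 to 0.614 over all its alternatives), and held in 3, 2, 1 and 1 of the 7 scalings. Those of miR-146a-5p (0.0702; 0.000143 to 0.712 over its alternatives), miR-126-3p (0.0631; 5.78e-05 to 0.0829) and miR-486-5p (-0.17, 0.263; 0.00226 to 0.455) ended by limma with quantile normalization, the first pair also without the 2 weakest sham mice (0.163 and 0.0829), and miR-486-5p also with median scaling (0.0520) and with the 3 most stable miRNAs (-0.22, 0.326). Of the 65 miRNAs, 29 had an unadjusted p under 0.05. The groups did not overlap for 5 of them (miR-10a-5p, miR-126-3p, miR-486-5p, miR-744-5p and miR-93-5p), against a chance share of 0.155% per miRNA. Leaving out sham mouse 2 lowered the count from 20 to 13, and leaving out sham mouse 1 ended the call of miR-146a-5p (0.70, limma adjusted p = 0.0520). The calls of miR-129-5p, miR-125a-5p, miR-22-3p, miR-24-3p and miR-20a-5p ended in 8, 9, 7, 7 and 10 of the 13 fits that left out 1 mouse.

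**Figure D2:**
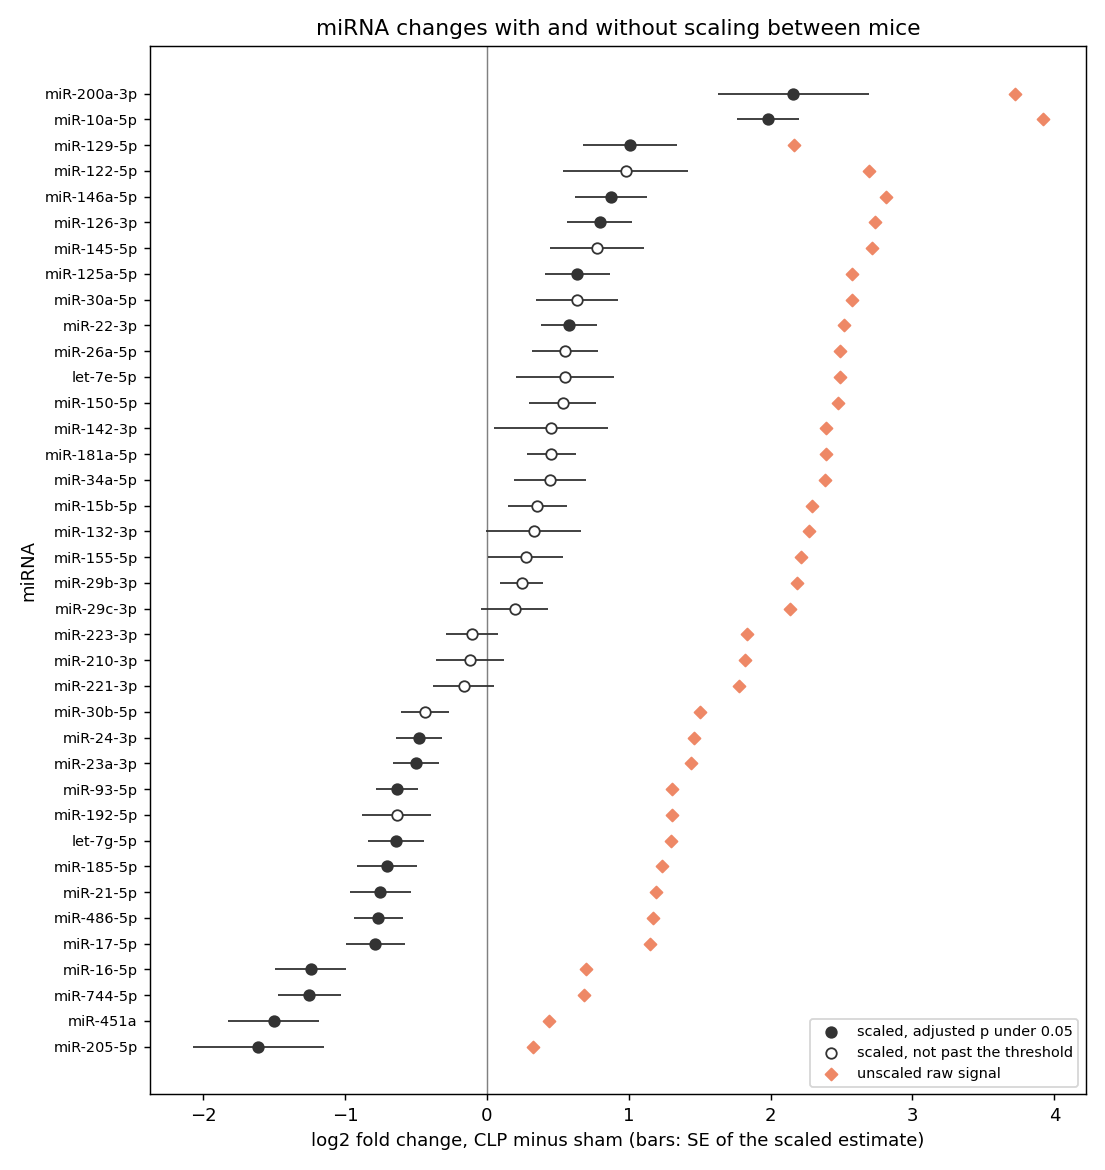
Log2 fold change (CLP minus sham, n = 8 and 5) of 38 named miRNAs after scaling (circles with SE bars, filled where the adjusted p was under 0.05) and on the unscaled raw signal (diamonds). After scaling miR-200a-3p lay at 2.16 and miR-451a at -1.50, whereas all 38 diamonds lie above 0, so every fall seen after scaling is positive unscaled, and miR-16-5p is positive under quantile normalization too.

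The slope of a miRNA on the level of the mouse differed between miRNAs. Within groups, log2 signal per log2 unit of level had a slope of 0.43 (SE 0.06) for miR-16-5p, 0.29 (SE 0.12) for miR-451a and 0.78 (SE 0.08) for miR-486-5p, against a median of 0.86 for the other miRNAs at 10 or more raw units. let-7e-5p (0.44) and miR-142-3p (0.48), outside the erythroid list, had low slopes too. The corresponding slopes were 1.32 for miR-10a-5p and 1.80 for miR-200a-3p. With the level as a covariate, a fit chosen after the data were seen, miR-10a-5p (1.37, SE 0.31, limma adjusted p = 0.0138) and miR-126-3p (1.23, SE 0.36, limma adjusted p = 0.0348) still passed. In that fit miR-205-5p (-2.62) and miR-24-3p (-0.87) passed too, whereas miR-200a-3p (0.29, SE 0.40), miR-16-5p (-0.14, SE 0.22) and miR-451a (-0.13, SE 0.30) did not.

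**Figure D3:**
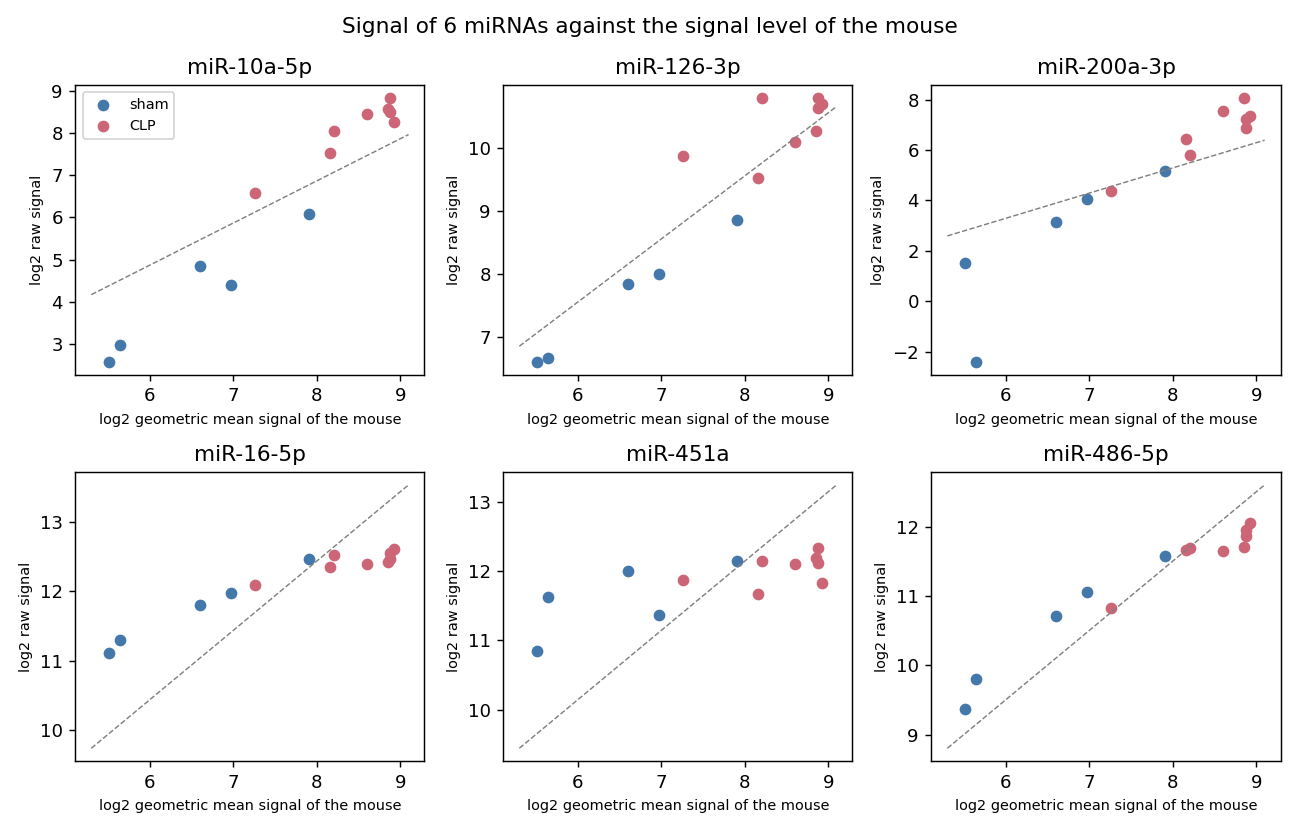
Log2 raw signal of 6 miRNAs in each mouse against the log2 geometric mean signal of that mouse (blue sham, n = 5; red CLP, n = 8), with a dashed line of slope 1. miR-16-5p and miR-451a rise less steeply than the line (within-group slopes 0.43 and 0.29), and miR-10a-5p of CLP mice lies above that of sham mice once level is a covariate (1.37).

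The third comparison asked whether miRNAs of one cell type or family moved together relative to the panel. Of the erythroid list, 3 of 5 tested members fell (miR-451a, miR-16-5p and miR-486-5p) and none rose, also when adjusted over the list alone (0 rose, 3 fell). Of the miR-17 seed family, 3 of 4 fell (miR-17-5p, miR-93-5p and miR-20a-5p), and the same 3 were the members that fell among the 5 of the miR-17-92 and paralog clusters; both counts were the same adjusted over the list alone. All of these fallers were positive on the unscaled signal, and miR-16-5p also under quantile normalization. By camera with a preset correlation, 0 of 12 lists passed after Benjamini-Hochberg adjustment, and 3 had an unadjusted p under 0.05: erythroid (0.0246, adjusted p = 0.0984), miR-17 seed family (0.0164, adjusted p = 0.0982) and miR-17-92 clusters (0.0131, adjusted p = 0.0982). For all 3, camera gave an adjusted p = 0.606 with an estimated correlation, and 0 lists had an unadjusted p under 0.05. The self-contained test fry, which does not compare a list with other miRNAs, called 4 lists, these 3 lower and lymphoid higher (adjusted p = 0.0418).

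Of the myeloid list, 1 of 4 members rose (miR-146a-5p), and of the lymphoid list 1 of 6 (the same miRNA, which both lists hold). The innate response list had 2 of 6 members that rose (miR-146a-5p and miR-125a-5p) and 1 that fell (miR-21-5p, positive unscaled). Of the platelet list, miR-126-3p rose and 2 of 5 fell (miR-21-5p and miR-24-3p, positive unscaled and the latter also with the 3 most stable miRNAs). Of the endothelial list, 1 of 2 rose (miR-126-3p), and miR-221-3p was at -0.16, with 1.77 unscaled. Of the epithelial list, miR-200a-3p rose and miR-205-5p fell among 4 members, the latter positive unscaled. In the neuronal list 1 of 2 rose (miR-129-5p), against 0.33 for miR-132-3p. All of these counts were the same adjusted over the list alone.

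Of the liver and gut list 0 of 3 members passed by limma, and of the miR-29 family 0 of 3 (miR-29b-3p 0.24, miR-29c-3p 0.20), the same adjusted over the list alone. The let-7 family had 1 of 5 that fell (let-7g-5p, positive unscaled), and the miR-15/16 seed family 1 of 3 (miR-16-5p, positive unscaled and under quantile normalization), against 0.36 for miR-15b-5p. miR-29b-3p and miR-15b-5p were each called higher under 4 of the 7 scalings (with the authors' values, limma adjusted p = 0.0421 and 0.0292). Both members of the miR-23/27/24 clusters fell (miR-23a-3p and miR-24-3p, positive unscaled, and miR-24-3p also with the 3 most stable miRNAs, of which miR-23a-3p is one). In the miR-30 family, miR-30a-5p (0.63) and miR-30b-5p (-0.44; 1.503 unscaled) did not pass over the panel, and 1 rose and 1 fell adjusted over the list alone. In the scaled fit, the single tested members of the mesenchymal (miR-145-5p) and miR-26 (miR-26a-5p, 0.55) lists passed, as higher, only adjusted over the list alone. With 1 member that is no adjustment: these are limma's unadjusted p = 0.0328 and 0.0306, and 29 of the 65 miRNAs had an unadjusted p under 0.05. Those of the miR-34 (miR-34a-5p, 0.45), miR-221 family (miR-221-3p) and hypoxia (miR-210-3p) lists passed neither way in that fit. Of the 7 scalings, 4 called miR-26a-5p higher, 2 miR-145-5p, 2 miR-34a-5p, and 1 each miR-221-3p and miR-210-3p. Each of these counts includes the unscaled signal, where 60 of 66 miRNAs rose, and for miR-221-3p and miR-210-3p it was the only such fit. Over the 9 other lists tested by camera the smallest adjusted p was 0.201, that of the lymphoid list, whose adjusted p = 0.606 with an estimated correlation. The median (0.10) and mean (-0.26) of the miR-15/16 seed family and the median (-0.24) and mean (0.04) of the liver and gut list differed in sign.

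The ratio of miR-451a to miR-23a-3p, commonly read as a marker of red cell RNA in plasma, was taken on raw values, so a factor per sample does not affect it. Its log2 mean was 1.02 ± 0.39 (SD, n = 8) in CLP and 2.03 ± 0.85 (SD, n = 5) in sham, a 2.01-fold lower ratio (exact two-sided permutation p = 0.0109, Benjamini-Hochberg adjusted 0.0218). The ratio also followed the level of the mouse within groups, since the slope on level was 0.29 for miR-451a and 1.02 for miR-23a-3p, so the group difference in ratio is not separate from the group difference in level. miR-16-5p and miR-451a together made up 17.0% ± 3.76 (SD, n = 8) of the raw signal in CLP and 32.2% ± 7.94 (SD, n = 5) in sham.

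All 68 miRNAs were above 0 in every mouse other than sham mouse 4, where 60 were, with 7 at 0 and 1 empty cell (difference in means 1.6, exact permutation p = 0.385). miRNAs above the 5th percentile of positive raw values numbered 65.9 ± 2.10 (SD, n = 8) in CLP and 61.0 ± 3.67 (SD, n = 5) in sham (exact permutation p = 0.00855, unadjusted). That cut is the same raw value in every mouse, so the count is not separate from the lower raw signal of sham mice. The median within-group SD of scaled log2 signal was 0.36 in CLP and 0.47 in sham, a log2 ratio of -0.39 that did not pass (exact permutation p = 0.0979, Benjamini-Hochberg adjusted 0.131). That p was 0.0328, 0.0455 and 0.0404 without CLP mouse 4, 6 and 8, respectively.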

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

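No test in this part was chosen after its result was seen. Of 82 sets of values from 1 group (named miRNAs and per-mouse measures), 4 held a mouse whose gap to the nearest of the others exceeded Dixon's 95% critical value, and chance alone picks out about 1 in 20 groups. CLP mouse 8 stood apart in 3 of them. Its geometric mean raw signal was the lowest of the CLP group, at 7.26 log2 units against 8.15 to 8.92 in the other CLP mice. After scaling, its miR-30a-5p was low, at 5.06 against 5.76 to 6.22, and its miR-223-3p was high, at 11.83 against 10.99 to 11.37. These 3 may not be separate, since the slope on level within CLP mice was 1.52 for miR-30a-5p and 0.56 for miR-223-3p. At a low level, scaling lowers the first and raises the second. Sham mouse 4 was the only mouse with fewer than 68 miRNAs above 0, at 60, with 7 at 0 and 1 empty cell. As the other sham counts were all 68, any lower count would have been picked out.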

How the results depend on the processing

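Tests chosen only after the result was seen were those without the 2 weakest sham samples, those on miRNAs at 10 or more raw units, those with level as a covariate, and the unscaled fits that left out mice; normexp was not run, since the table was taken as background subtracted. The higher raw signal held under every summary (1.49 to 1.94) and every mouse left out (1.69 to 2.28), as did the lower ratio of miR-451a to miR-23a-3p (-1.24 to -0.73); the spread ratio ranged from -0.51 to -0.28 and the difference in detected miRNAs from 0 to 2, and the latter passed only above the 5th percentile (4.88). The count of 20 changed miRNAs became 12 with quantile normalization, 60 unscaled, 10 with median scaling, 31 with the 3 most stable miRNAs and 8 with level as a covariate, and was 19 to 22 under the other scalings, floors, filters and tests, and 15 without the 2 weakest sham samples. Leaving out 1 mouse gave 13 to 22, the lowest without sham mouse 2, and 56 to 63 unscaled, against 37 without the 2 weakest sham samples. The median of all miRNAs was at 0.10 in the scaled fit, 0.15 with median scaling, 0.26 with the 75th percentile and with the authors' values, 0.59 with the 3 most stable miRNAs and 1.87 unscaled. Camera with an estimated correlation gave both miR-17 lists an adjusted p = 0.606 in the scaled fit. With the preset correlation it called 2 lists (both miR-17 lists) with the 75th percentile, with the authors' values and without sham mouse 3 (0 to 2 over mice left out), and 0 otherwise. Fry called 4 lists. The cause of these differences was not tested beyond the shift of the median and the level of the sample.

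With the replicate number as a block, 6 miRNAs passed instead of 20. Numbers 6 to 8 occur in CLP only, so those mice add nothing to the comparison in that fit, which has less power. The numbers do not pair mice: deviations of same-numbered samples correlated at 0.29, 0.03, 0.003, -0.34 and 0.11, and 1 of 5 sham samples correlated best with its own number.

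Of the named miRNAs, miR-10a-5p and miR-200a-3p kept their call under all scalings and with each mouse left out, although miR-200a-3p lost it with level as a covariate and ranged from 1.49 (without sham mouse 4) to 2.44 over mice left out. Direction turned in 47 fits of single miRNAs and 36 of lists, and the cause was not tested. Unscaled, these became positive: miR-205-5p 0.33, miR-451a 0.44, miR-744-5p 0.69, miR-16-5p 0.70, miR-17-5p 1.15, miR-486-5p 1.17, miR-140-3p 1.18, miR-21-5p 1.19, miR-185-5p 1.24, let-7g-5p 1.30, miR-192-5p 1.30, miR-93-5p 1.31, miR-20a-5p 1.43, miR-23a-3p 1.44, miR-24-3p 1.46, miR-30b-5p 1.503, miR-221-3p 1.77, miR-210-3p 1.82 and miR-223-3p 1.83. With quantile normalization so did miR-16-5p (0.14) and miR-223-3p (0.073). With the 75th percentile miR-221-3p, miR-210-3p and miR-223-3p were at 0.054, 0.101 and 0.114, and with the authors' values at 0.048, 0.095 and 0.108. With the 3 most stable miRNAs: miR-221-3p 0.38, miR-30b-5p 0.11, miR-24-3p 0.067, miR-210-3p 0.43, miR-223-3p 0.44 and, of the references, miR-23a-3p 0.046 and miR-20a-5p 0.038. At 10 or more raw units: miR-221-3p 0.041 and miR-223-3p 0.10. Without the 2 weakest sham samples: miR-221-3p 0.12, miR-132-3p -0.069 and miR-29c-3p -0.041. With level as a covariate: miR-221-3p 0.40, miR-223-3p 0.14, miR-122-5p -0.087, miR-132-3p -0.68, miR-29c-3p -0.025, miR-30a-5p -0.48 and miR-34a-5p -0.24. Over mice left out, miR-221-3p ranged from -0.31 to 0.0079, positive only without sham mouse 1.

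Calls of the 20 changed miRNAs ended as follows. With quantile normalization: miR-129-5p, miR-146a-5p, miR-126-3p, miR-125a-5p, miR-451a (-0.22), miR-16-5p, miR-486-5p (-0.17), miR-21-5p, miR-185-5p, let-7g-5p, miR-24-3p and miR-20a-5p. With median scaling: miR-129-5p, miR-125a-5p, miR-22-3p, miR-486-5p, miR-185-5p, let-7g-5p, miR-93-5p, miR-23a-3p, miR-24-3p and miR-20a-5p. With the 75th percentile and with the authors' values: miR-205-5p, miR-21-5p, miR-185-5p, let-7g-5p, miR-23a-3p, miR-24-3p and miR-20a-5p. With the 3 most stable miRNAs: miR-205-5p, miR-17-5p, miR-486-5p, miR-21-5p, miR-185-5p, let-7g-5p and miR-24-3p, besides the references miR-93-5p, miR-23a-3p and miR-20a-5p, for which the scaling forces it. Unscaled, all 13 that fell lost that call. Without the 2 weakest sham samples: miR-129-5p, miR-146a-5p, miR-126-3p, miR-125a-5p, miR-22-3p, miR-17-5p, miR-185-5p, let-7g-5p and miR-20a-5p. miR-125a-5p also lost its call in the exact permutation test (with miR-129-5p), with array weights (with miR-205-5p) and with trend and robust; miR-23a-3p, miR-24-3p and miR-20a-5p lost theirs at 10 or more raw units, where miR-200a-3p, miR-10a-5p, miR-129-5p and miR-125a-5p were not tested. miR-129-5p was also not tested with the higher floor, with no floor and with miRNAs detected in all samples. The block kept miR-200a-3p, miR-10a-5p, miR-451a, miR-744-5p, miR-16-5p and miR-486-5p, and level as a covariate kept miR-10a-5p, miR-126-3p, miR-205-5p and miR-24-3p. Named miRNAs that gained a call numbered 19 unscaled, 13 with the 3 most stable miRNAs, 7 at 10 or more raw units, 5 with the 75th percentile and with the authors' values, 4 with level as a covariate, 3 with array weights and without the 2 weakest sham samples, 2 with quantile normalization, with no filter and in the exact permutation test, and 1 with the higher floor and with miRNAs detected in all samples.

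None of the 6 lists whose mean shift against the other miRNAs turned was called by camera in any of these settings. The platelet shift (-0.021) was 0.072 unscaled, 0.083 with quantile normalization, 0.037 with the higher floor, 0.026 with miRNAs detected in all samples, 0.23 at 10 or more raw units and 0.155 with level as a covariate, and -0.11 to 0.020 over mice left out. The let-7 shift (-0.051) was 0.043 unscaled, 0.097 with quantile normalization, 0.0073 with the higher floor, 0.20 without the 2 weakest sham samples, 0.20 at 10 or more raw units and 0.70 with level as a covariate, and -0.23 to 0.11 over mice left out. The epithelial shift (0.29) was -0.073 unscaled, -0.089 with quantile normalization, -0.15 without the 2 weakest sham samples and -0.84 with level as a covariate, and -0.085 to 0.52 over mice left out. The liver and gut shift (0.018) was -0.155 without the 2 weakest sham samples and -0.71 with level as a covariate, and -0.069 to 0.16 over mice left out. The miR-15/16 shift (-0.29) was 0.13 with quantile normalization and 0.40 with level as a covariate, and the innate response shift (0.21) was -0.060 with level as a covariate.

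Calls of named miRNAs that ended without 1 mouse were miR-146a-5p (sham 1, 0.70), miR-185-5p (sham 1, -0.60; sham 2, -0.63), let-7g-5p (sham 2, -0.52; sham 4, -0.59) and miR-23a-3p (sham 2, -0.44; CLP 1, -0.48; CLP 5, -0.50; CLP 7, -0.46). That of miR-129-5p ended without sham 2, 4 or 5 or CLP 1, 4, 5, 6 or 7 (0.85 to 1.22 over all mice left out). For miR-125a-5p the mice were sham 1, 2 and 4 and CLP 1, 2, 3, 4, 5 and 7 (0.49 to 0.79), and for miR-22-3p sham 1 and 2 and CLP 3, 4, 5, 6 and 7 (0.46 to 0.69). For miR-24-3p they were sham 3 and 5 and CLP 1, 2, 5, 6 and 7 (-0.56 to -0.40), and for miR-20a-5p all other than sham 3, sham 5 and CLP 8 (-0.65 to -0.40). Raw means of miR-129-5p (1.496 units) and miR-125a-5p (8.65 units) in sham lie closest to the floor of the miRNAs that rose.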

Other observations

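The tests in this part were chosen only after the results were seen, other than those of splits of the samples. With the level of the sample as a covariate, 8 of 66 miRNAs passed in limma, and 4 of these were also called after scaling in the same direction. Besides miR-10a-5p and miR-126-3p, let-7e-5p (1.61) and miR-26a-5p (1.17) were higher in CLP. Lower were miR-205-5p (-2.62), miR-140-3p (-1.92), miR-192-5p (-1.54) and miR-24-3p (-0.87). The levels of the groups overlap only through sham mouse 5 and CLP mouse 8, so this fit leans on the slope assumed between them. miR-140-3p was named after its value was seen; after scaling it was at -0.76 (limma adjusted p = 0.0540), and unscaled at 1.18.

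Of 100 splits of the 13 mice into 5 and 8, 1 (the real one) called as many as 20 miRNAs after scaling, where the highest other called 6. Chance is thus an unlikely source of that count, although only 100 of all 1287 splits were drawn. The splits also do not separate CLP from the level of the sample, which differed between the groups. With level as a covariate, 4 of the 20 calls were kept. On the unscaled signal 1 of 100 reached the real count of 60, but the highest other split called 57. That split put the 2 brightest sham mice (sham 3 and sham 5, at 6.98 and 7.91 log2 units) with 6 CLP mice. Whether the level of the sample gave its calls was not tested over the splits. For lists the real count was 0, which all 100 of 100 splits reach by construction (the highest gave 4), so the splits say nothing about chance there.

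The higher raw signal in CLP may have more than one source. Lysis of red cells alone is argued against: the endothelial, liver and gut, epithelial and mesenchymal miRNAs had a median unscaled change of 1.74, and 9 of 10 of them rose (1.77, and 8 of 9, without miR-885-5p, which has no mouse gene of its name). That is close to the share of the whole panel (60 of 66, median 1.87), so the rise was not particular to these lists. Of these miRNAs, miR-126-3p is also on the platelet list. A common factor per sample, such as RNA input or amplification yield, cannot be told apart from a larger amount of exosomal RNA in septic plasma. The 2 tested probes with no mouse gene of their name (miR-422a 1.92, miR-885-5p 1.70; median 1.81) were higher too, but they are few and cross-hybridization to a related miRNA would give the same. More vesicles or more miRNA per vesicle in sepsis stays open and was not tested.

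The relative falls of miR-16-5p, miR-451a and miR-486-5p could come from compression at high intensity. Their median within-group slope on the level of the sample was 0.43, where 1 is proportional, and none of the 3 passed once level was a covariate: miR-16-5p went from -1.24 (SE 0.25) to -0.14 (SE 0.22), miR-451a from -1.50 (SE 0.32) to -0.13 (SE 0.30) and miR-486-5p from -0.76 (SE 0.17) to -0.34 (SE 0.25). The estimates of miR-16-5p and miR-451a shrank with little change in error, whereas for miR-486-5p the error grew as well, so its lost call is weaker evidence. The fit with level subtracts the slope times the difference in level, where scaling subtracts the whole difference. A slope below 1 thus raises the estimate by itself, so the lost calls are not evidence separate from the slopes. Low slopes also occurred in dimmer miRNAs such as let-7e-5p (0.44). The fit with level ended 16 of the 20 scaled calls, and dimmer miRNAs such as miR-146a-5p (0.87 to 0.23) and miR-185-5p (-0.70 to -0.18) shrank too. Losing the call in that fit is thus not particular to bright miRNAs. A fixed red cell background under a varying vesicle signal stays open: the other miRNAs above 2000 raw units had a median slope of 0.79 within CLP mice, between a proportional and a flat response. That is close to the median of 0.86 within CLP mice for miRNAs at 10 or more raw units outside these 3. Over 40 miRNAs, the Spearman correlation of slope with mean signal was -0.41 within CLP and 0.18 within sham. The slope of miR-486-5p within groups (0.78, SE 0.08) also lay near that of the other miRNAs (0.86). A true fall of erythroid miRNAs in septic plasma was not tested separately.

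The rise of miR-10a-5p was set against 2 technical explanations. With level as a covariate at 1 common log2 slope, the change was 1.37 (SE 0.31, limma adjusted p = 0.0138, against at most 0.000126 when single mice were left out of the scaled fit). Such a slope did not account for all of the rise in that fit. A curved response to level was not tested, and the levels of the groups overlap only through sham mouse 5 and CLP mouse 8. Sham values at the floor are argued against, since the lowest sham value was 2.85 times the unscaled floor. That floor is a percentile of these data and not a measured background, so the response at low signal was not tested. Cross-hybridization with a related miRNA was not tested. A candidate explanation is a true relative increase of miR-10a-5p in exosomes after CLP, a hypothesis found and tested on the same 13 mice, with the 2 columns of unsettled identity both in the CLP group.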
